A study of Mus musculus with 6 samples.

How the data were processed

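RNA from the nucleus gigantocellularis of C57/Bl6 mice was measured in 6 libraries, 3 input and 3 bound, each made from 5 to 6 pooled animals of both sexes aged 8 to 16 weeks, per the labels. Per the labels' protocols, translating ribosomes were affinity purified after the dissection and libraries were built with a SMARTer low-input kit. The values are read counts per gene made by the authors: per the submitters' processing notes, bases were called with CASAVA 1.8.2, reads aligned with STAR 2.3 and counted with featureCounts on mm10 and GRCm38. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited file also gives the merged exon length of each gene, per the file headers.

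The table holds 39017 genes by Ensembl identifier, of which 37607 were given a symbol from the GENCODE M21 annotation of GRCm38, and the rest kept their identifier. Genes were kept by edgeR's filterByExpr on the 2 groups, which left 16286, and scaled by TMM factors. Bound was tested against input by edgeR's quasi-likelihood F test (glmQLFit with robust settings) with no block, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. A log2 fold is bound minus input, an SE is derived from the F statistic, and levels are in CPM, the counts of a gene per 1000000 scaled counts of its library. A ratio of a pair is the difference of log2 CPM (prior count 2) between the bound and input libraries with the same label. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

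The main test, the alternatives planned for it, 41 gene lists and the rule for named genes were set before the data were examined. Lists were tested on log2 CPM with limma's camera against all other genes with a preset correlation of 0.01, then with an estimated correlation and with fry. Fry asks whether a list's genes move 1 way on balance. The lists were neuron general, long axon neuron, glutamatergic, gaba glycinergic, cholinergic, monoaminergic, neuropeptides, peptide hormone receptors, amine receptors, glutamate receptors, gaba glycine receptors, synaptic vesicle, voltage gated channels, nitric oxide, oligodendrocyte, opc, astrocyte, microglia, endothelial, pericyte smooth muscle, ependymal choroid, schwann peripheral, blood, lymphocyte neutrophil, cerebellum, forebrain thalamus, hindbrain tf, ascending arousal, immediate early, interferon antiviral, injury inflammation, unfolded protein, oxphos nuclear, glycolysis, cholesterol synthesis, mitochondrial encoded, nuclear noncoding, small nucleolar hosted, ribosomal protein, replication histones, cell cycle. The small nucleolar hosted list had under 3 tested members and was given values and no test. Some genes are in more than 1 list, so the lists are not all independent. The named genes were 16 fixed ones, up to 10 genes per direction past the threshold with all 3 bound libraries on 1 side of all 3 inputs, and up to 4 members of each list with the smallest p. Since 0 genes qualified in either direction, the 5 with the smallest p per direction stand in for the second group, reported as not passing. Predicted genes, pseudogenes and genes under a mean log2 CPM of 3 were left out of that group. A fixed gene is not reported here.

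Libraries share the labels A, B and 1 across the groups. Deviations from the group means across genes correlated at 0.316 for the A libraries, 0.284 for B and 0.482 for 1, each over 0.1, so the labels were taken to pair the libraries. Input A correlated as well with bound B (0.327), and input B with bound A at 0.202, also over 0.1. Input 1 correlated at -0.349 with bound A and -0.414 with bound B. The correlations thus set label 1 apart but cannot part A from B. The Y-linked gene Ddx3y was at 12.6, 29.0 and 112 CPM in input A, B and 1 and 15.1, 26.3 and 139.7 CPM in bound A, B and 1. Other sex-linked genes went apart within labels: Kdm5d was at 2.37 and 2.47 CPM in input A and B and 6.62 and 9.42 CPM in bound A and B, Uty at 7.95 CPM in input B and 1.90 CPM in bound B, and Xist at 1.14 and 0 CPM in input A and B and 15.5 and 16.2 CPM in bound A and B. The pairing of A and B therefore rests on the shared labels alone. No protocol states it, and the sex-linked genes do not settle it. Pair ratios and fits with the block depend on the pairing. No 2 libraries of a group agreed within counting noise, the closest being input A and B with a chi-square of 9.62 per degree of freedom.

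The edgeR test was run on simulated counts of 16286 genes with 200 changed. Without a block it recovered 0% of genes changed 2-fold, 36% at 4-fold, 76% at 8-fold and 94% at 16-fold, with 2 of 105 calls false. DESeq2 recovered 14%, 78%, 90% and 98%, with 60 of 200 calls false. With the block edgeR recovered 22%, 80%, 96% and 100%, with 17 of 166 calls false, and DESeq2 32%, 92%, 98% and 100%, with 64 of 225 calls false.

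The alternatives were RLE and upper-quartile factors, leaving out mitochondrial and structural RNA genes, no low-count filter, a mean of at least 5 CPM, DESeq2 with default settings, limma-voom, glmTreat against a fold of 1.5, the replicate block, and leaving out each library and each label. Chosen after seeing the data were DESeq2 with the replicate block, edgeR, DESeq2 and camera with the block and the GC and length trends of each library removed, DESeq2 on the A and B pairs alone, camera with an estimated correlation and the block, and DESeq2 with its independent filtering at 0.05. The last was run first by mistake in place of the planned default of 0.1, and the text gives the default. DESeq2 and glmTreat were not run for lists. Counting intervals are exact binomial intervals at 95% and cover counting error only, since amplified reads without molecular identifiers are not independent molecules.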

Results

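RNA was sequenced from the nucleus gigantocellularis, a large-celled part of the medullary reticular formation, of C57/Bl6 mice whose central thalamus had received a canine adenovirus carrying a green fluorescent protein gene. The virus is taken up by axon endings and carried back to the cell body, so the labelled cells are those that send axons to the injected region. Input libraries hold total RNA of the dissected nucleus and bound libraries hold RNA from ribosomes purified from the labelled cells, with 3 libraries in each group, labelled A, B and 1. Summed gene counts were 11062549, 10693388 and 21364548 in input A, B and 1 and 11167420, 11142741 and 20350878 in bound A, B and 1. The comparison sets ribosome-bound RNA of the labelled neurons against total RNA of the nucleus, those neurons included. It cannot part cell type from ribosome association or from background of the purification. No purification from unlabelled tissue is among the samples. The libraries labelled 1 stood apart from the rest. On a first principal component holding 56.7% of the variance, bound 1 lay at 153, input 1 at 42.4 and the other 4 libraries between -51.5 and -45.4.

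Ribosome-bound RNA carried more of the genes for voltage-gated ion channels and of vessel endothelium than the RNA of the whole nucleus. It carried less of the genes of microglia, oligodendrocytes and astrocytes. The voltage-gated channel genes, which set the firing of neurons, rose in bound RNA by a median log2 fold of 0.47 with 37 of 44 higher, endothelial genes rose by 1.10 but had a median ratio of -0.43 in pair 1, and microglia genes fell by a median of 0.91 on the log2 scale with 21 of 22 lower, or by 0.41 without both libraries labelled 1 (camera adjusted p = 1.3e-06, 9.6e-06, 6.0e-11 and 4.5e-05). None of the calls over all 6 libraries held when the correlation was estimated. There the adjusted p was 0.443 for channels, 0.654 for endothelium and 0.556 for microglia. The microglia fit without both libraries labelled 1 was not run with an estimated correlation. Nos3, the endothelial nitric oxide synthase, was at 4.70 ± 1.95 CPM in input and 21.9 ± 8.76 CPM in bound (mean ± SD, n = 3) and was higher in bound RNA in all 3 pairs of libraries that share a label. No single gene passed the edgeR test in either direction, and genes expressed by most neurons had median ratios of 0.01, -0.01 and 0.65 in pairs A, B and 1.

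**Figure D1:**
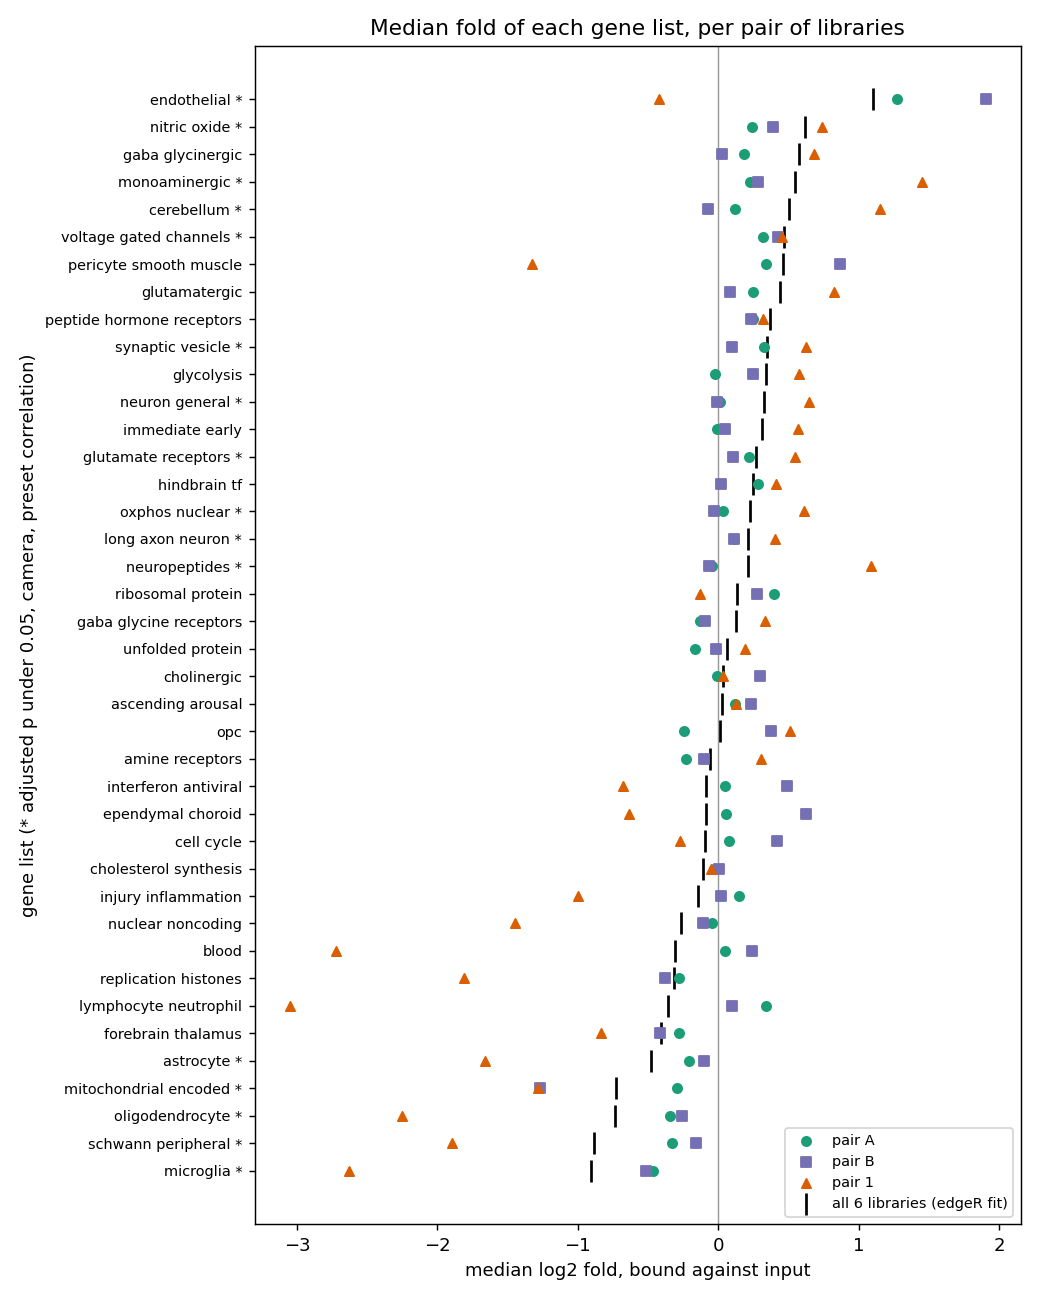
Median log2 fold of each of 40 gene lists between bound and input RNA (x axis). Each list has a line on the y axis, a vertical bar for the fit to all 6 libraries and a point for each pair of libraries with the same label. Microglia genes had a median ratio of -0.46 in pair A, -0.52 in pair B and -2.63 in pair 1, and endothelial genes of 1.27, 1.90 and -0.43.

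Genes of excitability and of transmitter release were higher as groups. Among the channels, the potassium channel gene Kcnd3 (0.96 ± 0.28), and the sodium channel genes Scn8a (0.87 ± 0.29) and Scn1a (0.83 ± 0.35) had the smallest p (log2 fold ± SE). In all, 23 of the 44 members were higher in each of the 3 pairs. The channel list passed in each of the 9 fits that left out a library or a label, with a median of 0.27 without both libraries labelled B. Vesicle release genes rose (median log2 fold 0.34, camera adjusted p = 9.3e-04, and adjusted p = 0.443 with an estimated correlation), with 21 of 26 higher and pair medians of 0.33, 0.10 and 0.62 in A, B and 1. Of single members, edgeR without both libraries labelled 1 called 4 higher and 4 lower. The active-zone scaffold genes Bsn (1.29 ± 0.23) and Pclo (1.22 ± 0.37) led them, and Bsn was the 1 member called when p was adjusted over the list alone. Genes expressed by most neurons rose (median log2 fold 0.33, camera adjusted p = 0.0149, and adjusted p = 0.701 with an estimated correlation), with a median ratio of 0.01, -0.01 and 0.65 in pairs A, B and 1. Within this list, Snap25, which codes for a membrane fusion protein of the nerve ending, had a log2 fold of -0.12 ± 0.52 and Rbfox3, the gene of the neuronal nuclear antigen NeuN, one of 0.10 ± 0.23. Snap25 turned to higher and Rbfox3 to lower under some of the other settings. Without both libraries labelled 1, edgeR called Snap25 lower (-0.39, adjusted p = 0.0423), as did DESeq2 on the A and B pairs alone (3.0e-05). Neurofilament and other projection-neuron genes rose (median log2 fold 0.21, camera adjusted p = 0.0236, and adjusted p = 0.443 with an estimated correlation), led by the heavy neurofilament gene Nefh (0.99 ± 0.30). Scn8a and Scn1a, named above for the channels, are also in the projection-neuron list and among its leading members, so it is not separate evidence. Glutamate receptor genes rose (median log2 fold 0.27, camera adjusted p = 0.0156, and adjusted p = 0.443 with an estimated correlation), led by the NMDA receptor subunit gene Grin2b (1.39 ± 0.35). Without bound replicate 1 the camera adjusted p was 0.148 for vesicle release, 0.882 for general neuronal, 0.229 for projection-neuron and 0.284 for glutamate receptor genes. Without both libraries labelled 1 it was 0.238, 0.791, 0.238 and 0.326. Without input replicate 1 it was 0.142 for projection-neuron and 0.134 for glutamate receptor genes, and without input replicate A 0.0544 for general neuronal genes. The vesicle release median was 0.15 without bound replicate 1, and the general neuronal one 0.02 without bound replicate 1 and -0.01 without both libraries labelled 1. The projection-neuron median was 0.37 without input replicate B, 0.12 without input replicate 1, 0.32 without bound replicate 1 and 0.11 without both libraries labelled 1, and the glutamate receptor one 0.42 without input replicate B, 0.18 without input replicate 1 and 0.11 without both libraries labelled 1.

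All 5 amino acid transmitter genes fixed in advance had a higher value in bound RNA, and none passed the edgeR threshold over all 6 libraries. Without both libraries labelled 1, edgeR called Slc6a5 (adjusted p = 0.0242) and Gad1 (0.0390), and DESeq2 with the replicate block called Gad1 (0.0138). The vesicular glutamate transporter gene Slc17a6 was at 178 ± 47.0 CPM in input and 251 ± 106 CPM in bound, and the glycine transporter gene Slc6a5 at 185 ± 43.8 CPM in input and 273 ± 43.6 CPM in bound (mean ± SD, n = 3). The log2 folds (± SE) were Slc17a6 (0.49 ± 0.36), Slc6a5 (0.56 ± 0.27), Slc32a1 (0.59 ± 0.40), Gad1 (0.87 ± 0.50) and Gad2 (0.87 ± 0.60). As groups, the 6 tested glutamatergic genes had a median log2 fold of 0.44 (camera adjusted p = 0.118). That median lies between the receptor gene Grin1 (0.44 ± 0.35) and Slc17a8 (0.44 ± 1.58). The latter gene was near the floor, at 0.99 CPM in input and 1.36 CPM in bound. GABA and glycine genes had a median of 0.58 (camera adjusted p = 0.579). Members of the GABA and glycine list went both ways, since the glial glycine transporter gene Slc6a9 had a log2 fold of -0.85 ± 0.23. Chat, which makes acetylcholine, had a log2 fold of 0.34 ± 0.34. The 5 acetylcholine genes had a median of 0.04, a mean of -0.00724 and a camera direction of lower (adjusted p = 0.966). Serotonin and catecholamine genes rose (median log2 fold 0.54, camera adjusted p = 0.00284, and adjusted p = 0.556 with an estimated correlation). Their camera adjusted p was 0.0805 without bound replicate 1 and 0.177 without both libraries labelled 1. Their pair medians were 0.22, 0.29 and 1.45 in A, B and 1, and their median was 0.87 without input replicate 1 and 0.19 without bound replicate 1. The enzyme genes of noradrenaline synthesis, Dbh (2.04 ± 0.55) and Th (2.40 ± 0.74), and the noradrenaline transporter gene Slc6a2 (2.62 ± 0.84) led this list, each higher in all 3 pairs. Dbh was at 19.0 ± 6.55 CPM in input and 78.5 ± 54.3 CPM in bound and Th at 19.8 ± 8.80 CPM in input and 105 ± 98.8 CPM in bound. Neuropeptide genes rose (median log2 fold 0.21, camera adjusted p = 0.0210, and adjusted p = 0.654 with an estimated correlation), led by Sst (1.58 ± 0.45), Gal (1.53 ± 0.44) and Npy (1.56 ± 0.50). Their median was 0.33 without input replicate A, 0.42 without input replicate B, 0.03 without input replicate 1, 0.33 without bound replicate A and -0.09 without both libraries labelled 1. Their pair 1 median was 1.09 against -0.04 in pair A and -0.07 in pair B. With the replicate block the neuropeptide call ended (adjusted p = 0.0653), as it did without input replicate 1 (0.681), without bound replicate 1 (0.346) and without both (0.791, median -0.09).

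**Figure D2:**
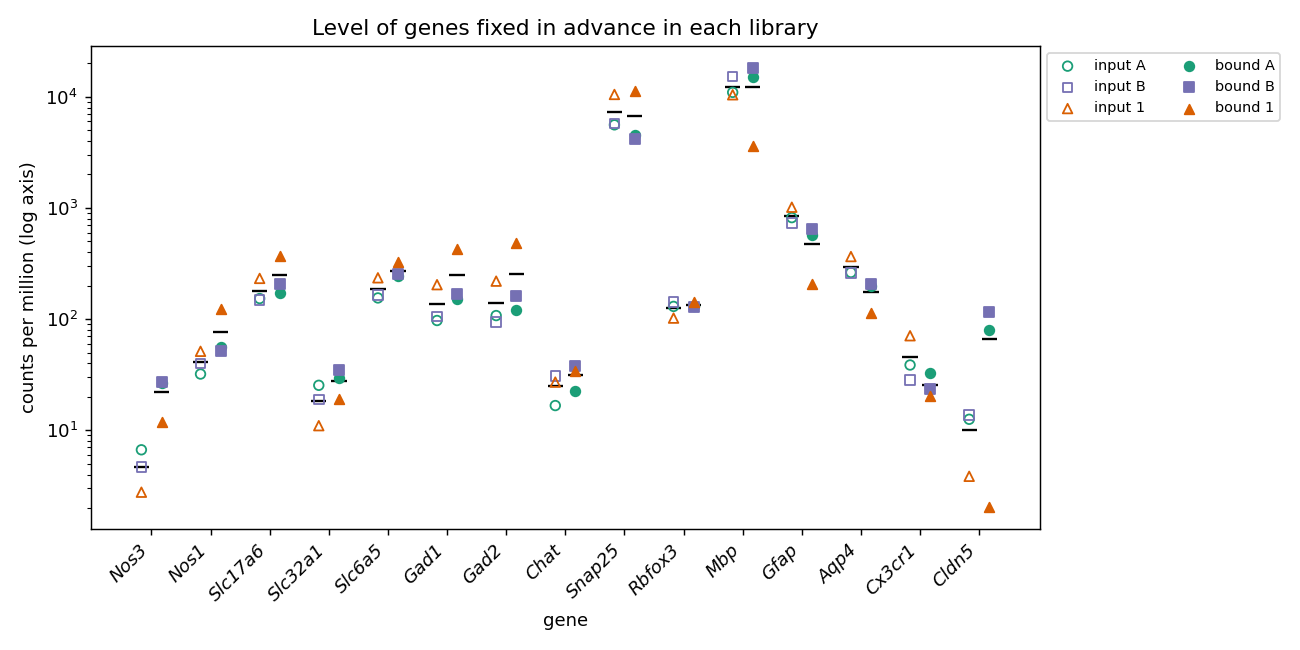
Level in CPM (log y axis) of genes fixed in advance (x axis) in each library, with open symbols for input, filled symbols for bound and a horizontal bar for each group's mean of 3 libraries. Nos3 in the 3 bound libraries lay above its 3 input libraries, while Cldn5 was above input in bound A and B and below it in bound 1.

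Nos3 (ENSMUSG00000028978, chromosome 5, 24364810 to 24384474, GRCm38) had a log2 fold of 2.22 ± 0.50 between bound and input, with ratios of 1.97, 2.52 and 2.03 in pairs A, B and 1. Its counts were 76, 51 and 59 in input A, B and 1 and 304, 317 and 212 in bound A, B and 1. The edgeR test across all genes gave it an adjusted p of 1.00, DESeq2 gave 0.0234, and edgeR without both libraries labelled 1 gave 0.0181. Over its alternatives the adjusted p of Nos3 ran from 7.0e-07 to 1.00, and its log2 fold from 1.95 to 2.56. With the replicate block, edgeR gave Nos3 an adjusted p of 0.291 and DESeq2 gave it none. The last 294 exon bases of Nos3 overlap Atg9b on the other strand. The strand setting of the counting is not given in the sources used here, so reads in that stretch cannot be assigned to 1 of the genes. Nos1, the neuronal synthase, was at 41.1 ± 9.69 CPM in input and 76.9 ± 39.4 CPM in bound (mean ± SD, n = 3), a log2 fold of 0.90 ± 0.40 that did not pass. Nitric oxide and cyclic GMP genes rose as a group (median log2 fold 0.62, camera adjusted p = 0.0497, and adjusted p = 0.654 with an estimated correlation), with 15 of 21 higher. Their median was 0.22 with the replicate block (adjusted p = 0.0217, and adjusted p = 0.740 with an estimated correlation and the block) and 0.36 without input replicate A, 0.34 without input replicate B, 0.14 without bound replicate 1, 0.34 without both libraries labelled B and 0.25 without both libraries labelled 1. The pair medians were 0.24, 0.39 and 0.74 in A, B and 1. Adjusted over the list alone, 2 members passed, Nos3 and the chaperone gene Hsp90aa1 (1.33 ± 0.32), against 0 over all genes. Hsp90aa1 is also a member of the unfolded protein list. The published study took up Nos3 from these samples, so this list is not independent evidence of its direction. Of the 9 fits that left out a library or a label, the list passed in 2, those without bound replicate A and without both libraries labelled A. Its camera adjusted p elsewhere ranged from 0.0613 without input replicate 1 to 0.448 without bound replicate 1.

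Genes of oligodendrocytes, astrocytes and microglia were lower in bound RNA, while oligodendrocyte precursor genes had a median log2 fold of 0.01. Oligodendrocyte and myelin genes fell (median log2 fold -0.74, camera adjusted p = 8.1e-07, and adjusted p = 0.654 with an estimated correlation), with 22 of 24 lower. Mbp, the myelin basic protein gene, was at 12176 ± 2601 CPM in input and 12292 ± 7705 CPM in bound (mean ± SD, n = 3) and had ratios of 0.47, 0.26 and -1.54 in pairs A, B and 1. Astrocyte genes fell (median log2 fold -0.48, camera adjusted p = 6.7e-05, and adjusted p = 0.654 with an estimated correlation), with the water channel gene Aqp4 (-0.76 ± 0.31) and the filament gene Gfap (-0.84 ± 0.44) among them. Microglia genes had 18 of 22 members lower in all 3 pairs, led by the purine receptor gene P2ry12 (-1.61 ± 0.41), and Cx3cr1 had a log2 fold of -0.84 ± 0.40. Genes of the Schwann and peripheral list, of whose 8 members 5 were tested, fell (median log2 fold -0.88, camera adjusted p = 0.00153, and adjusted p = 0.443 with an estimated correlation). Of these, 5 of 5 were lower and 1 was called when adjusted over the list alone. That member was Fgl2 (-1.59 ± 0.40), which codes for a secreted fibrinogen-like protein. The drop was deepest in pair 1, where the median ratio was -2.26 for oligodendrocyte, -1.66 for astrocyte and -1.90 for Schwann and peripheral genes. These medians were -0.34, -0.21 and -0.33 in pair A and -0.26, -0.10 and -0.16 in pair B. Without bound replicate 1 the camera adjusted p was 0.0805 for oligodendrocyte, 0.448 for astrocyte and 0.346 for Schwann and peripheral genes. Without both libraries labelled 1 it was 0.272 for astrocyte and 0.238 for Schwann and peripheral genes. The oligodendrocyte median was -0.35 without bound replicate 1 and -0.30 without both libraries labelled 1. The Schwann and peripheral one was -0.29 without bound replicate 1 and -0.22 without both libraries labelled 1. The astrocyte median was -0.76 without bound replicate B, -0.10 without bound replicate 1, -0.76 without both libraries labelled B and -0.10 without both libraries labelled 1. The microglia list passed in each of these fits, with a median of -0.52 without bound replicate 1 and -0.41 without both libraries labelled 1.

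Of 13 protein-coding genes of the mitochondrial genome, which cytosolic ribosomes do not translate, only 7 passed the low-count filter, and the rest went untested. The treatment of reads that map to several places is not given, so low counts of the rest need not mean low expression. Those tested fell (median log2 fold -0.73, camera adjusted p = 9.3e-04, and adjusted p = 0.654 with an estimated correlation), with 7 of 7 lower in the fit and in each of the 3 pairs. Counted reads of the mitochondrial chromosome, which may miss such reads, made up 3.25%, 3.12% and 1.68% of input A, B and 1 and 2.36%, 1.29% and 0.415% of bound A, B and 1. Nuclear-encoded respiratory chain genes rose (median log2 fold 0.22, camera adjusted p = 0.00141, and adjusted p = 0.701 with an estimated correlation), with 60 of 64 higher, led by Ndufb9 (0.62 ± 0.22). Without bound replicate 1 the mitochondrial list had a camera adjusted p of 0.148 and the nuclear-encoded list one of 0.684 with the direction turned. Without both libraries labelled 1 the latter had 0.833. Without both libraries labelled B the mitochondrial list had a camera adjusted p of 0.0596. The mitochondrial median was -1.45 without bound replicate A, -0.33 without bound replicate 1 and -1.28 without both libraries labelled A. The nuclear-encoded median was 0.36 without bound replicate A, 0.34 without bound replicate B, -0.03 without bound replicate 1 and 0.00 without both libraries labelled 1, with pair medians of 0.03, -0.03 and 0.61 in A, B and 1. Glycolysis genes had a median log2 fold of 0.34 (adjusted p = 0.0542) and rose with the replicate block (adjusted p = 0.00853, and adjusted p = 0.740 with an estimated correlation and the block). Ribosomal protein genes had a median of 0.13 (adjusted p = 0.0524) and rose with the block (adjusted p = 0.0217, and adjusted p = 0.740 with an estimated correlation and the block).

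Genes of blood vessel endothelium rose (median log2 fold 1.10, camera adjusted p = 9.6e-06, and adjusted p = 0.654 with an estimated correlation), with 26 of 27 higher in the fit. The median ratio was 1.27 in pair A and 1.90 in pair B but -0.43 in pair 1. The vascular growth factor receptor gene Flt1 (2.95 ± 0.74) and the tight junction gene Cldn5 (2.72 ± 1.20) were among the members, and Cldn5 had ratios of 2.66, 3.06 and -0.86 in pairs A, B and 1. The median was 0.66 with the replicate block (adjusted p = 9.1e-05, and adjusted p = 0.740 with an estimated correlation and the block). Without bound replicate B the median was 0.47 and the camera adjusted p 0.0829, and without both libraries labelled B 0.53 and 0.0624. Pericyte and smooth muscle genes did not pass over all libraries (median 0.46, adjusted p = 0.403), with a median ratio of -1.33 in pair 1. They rose without input replicate 1 (0.0356), without bound replicate 1 (0.00322) and without both (4.5e-05). Over all libraries they had adjusted p = 0.845 with an estimated correlation, and with the replicate block their median turned to -0.06 (0.493, and adjusted p = 0.953 with an estimated correlation and the block). Cerebellar genes rose (median log2 fold 0.51, camera adjusted p = 0.0245, and adjusted p = 0.654 with an estimated correlation), led by the calcium release channel gene Itpr1 (0.64 ± 0.24), which many brainstem neurons also express. Their pair medians were 0.12, -0.07 and 1.15 in A, B and 1, and their median was 0.08 without bound replicate 1 and 0.06 without both libraries labelled 1. Without bound replicate 1 their camera adjusted p was 0.684, without input replicate 1 0.109, without input replicate A 0.101 and without both libraries labelled 1 0.686.

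**Figure D3:**
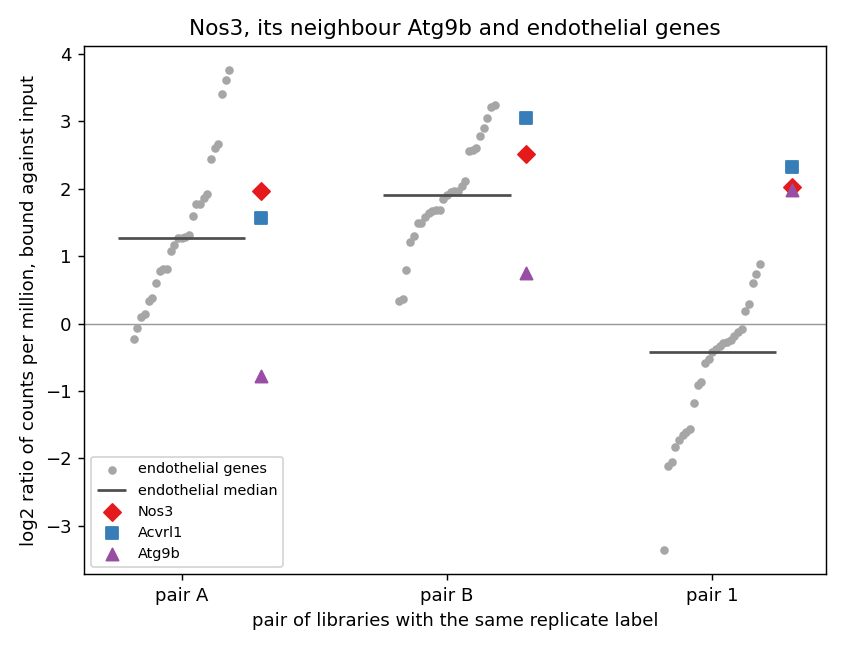
Log2 ratio of bound to input (y axis) in pairs A, B and 1 (x axis), with grey points for the 27 endothelial genes, a line for their median and symbols for Nos3, Acvrl1 and Atg9b. Nos3 and Acvrl1 were above 0 in each pair, while the endothelial median was below 0 in pair 1.

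At the level of single genes, 0 of 16286 genes were higher and 0 lower by edgeR's quasi-likelihood test, with 635 at an unadjusted p under 0.05, 444 of them higher. DESeq2 called 36 higher and 4 lower, and limma-voom 0 (793 at an unadjusted p under 0.05). With the replicate block, edgeR called 0 (1460 at an unadjusted p under 0.05) and DESeq2 238 higher and 74 lower. Leaving out both libraries labelled 1 raised the edgeR count to 306 higher and 99 lower, 39 of the 40 DESeq2 genes among them. That fit reused the A and B libraries, so the overlap is not independent. The 5 named genes with the smallest p among those higher in bound RNA were the ubiquitin ligase gene Ubr4 (1.55 ± 0.23), the dynein heavy chain gene Dync1h1 (1.69 ± 0.29), the synaptic gene Dmxl2 (1.22 ± 0.22), Bsn (1.29 ± 0.23) and Acvrl1 (2.33 ± 0.42), a receptor of vessel endothelium. The 5 among those lower were the mitochondrial transfer RNA gene mt-Ty (-2.40 ± 0.44), the cytochrome oxidase assembly gene Coa5 (-1.09 ± 0.25), the zinc finger gene Zfp24 (-1.03 ± 0.24) and the microglial gene P2ry12 (-1.61 ± 0.41), followed by Tnfaip8, which had ratios of -0.97, -1.08 and -0.95 in pairs A, B and 1. None of these 10 passed the edgeR test. DESeq2 called Ubr4 (4.9e-06), Dync1h1 (9.7e-04), Dmxl2 (9.7e-04), Bsn (0.00118), Acvrl1 (0.00114), mt-Ty (0.00118), Coa5 (0.0404) and Zfp24 (0.0484), given as adjusted p. All 40 DESeq2 genes kept 1 direction in the 3 pairs, which choosing them on these same libraries favours. Over all genes, the 3 bound and 3 input libraries did not overlap for 11.8% of genes, where chance gives 10%, and 35.4% of genes had 1 sign in all 3 pairs, where chance gives 25%.

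The other lists did not pass. Values were higher for receptors of arousal peptides and steroids (median 0.37, adjusted p = 0.0542), hindbrain transcription factors (median 0.25, adjusted p = 0.290), and activity-induced genes (median 0.31, adjusted p = 0.409). They were also higher for GABA and glycine receptors (median 0.13, adjusted p = 0.857), unfolded protein response genes (median 0.07, adjusted p = 0.566), developmental genes of reticular neurons (median 0.03, adjusted p = 0.375) and oligodendrocyte precursor genes (median 0.01, adjusted p = 0.631). Values were lower for monoamine and acetylcholine receptors (median -0.06, adjusted p = 0.913), ependymal and choroid plexus genes (median -0.09, adjusted p = 0.857), dividing-cell genes (median -0.10, adjusted p = 0.610), and cholesterol synthesis genes (median -0.11, adjusted p = 0.566). They were also lower for injury genes (median -0.14, adjusted p = 0.401), forebrain and thalamus genes (median -0.41, adjusted p = 0.279), replication histones (median -0.32, adjusted p = 0.0839), red cell genes (median -0.31, adjusted p = 0.118) and lymphocyte and neutrophil genes (median -0.36, adjusted p = 0.0839). In pair 1 the median ratio of red cell genes was -2.72 and that of lymphocyte and neutrophil genes -3.05. Interferon genes had a median of -0.08, a mean of 0.00546 and a camera direction of lower (adjusted p = 0.966). With the preset correlation they turned to higher past the threshold without input replicate 1 (0.0210) and without both libraries labelled 1 (0.00585). Over all libraries they had adjusted p = 0.988 with an estimated correlation. Nuclear noncoding RNAs had a median of -0.27, a mean of 0.22 and a camera direction of lower (adjusted p = 0.343). Of the 16 members of the small nucleolar hosted list only Rn7sk passed the low-count filter, at a log2 fold of 0.78 ± 1.24. Apart from Bsn, Nos3, Hsp90aa1 and Fgl2, 0 members of any list passed when edgeR's p was adjusted over the list alone, and 0 passed over all genes. With the replicate block the counts adjusted over the list alone were as large or larger in each list, with 7 of 7 mitochondrial, 5 of 8 GABA and glycine, 4 of 19 projection-neuron, 3 of 10 serotonin and catecholamine, and 3 of 26 vesicle release genes. They were 2 each for neuropeptide, microglia and nitric oxide genes. They were 1 each for channel, Schwann and peripheral, forebrain and thalamus and unfolded protein response genes, and 0 for the other lists.

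Of the 40 lists tested by camera with a preset correlation, 11 rose and 5 fell. None passed with an estimated correlation (smallest adjusted p = 0.443) and none by fry (smallest adjusted p = 0.394). Without bound replicate 1, 4 lists passed with the preset correlation, and without both libraries labelled 1, 8.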

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

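The fits that combine DESeq2 with the block, remove GC and length trends or run DESeq2 on the A and B pairs alone, or set its independent filtering at 0.05, and camera with an estimated correlation and the block, were chosen after seeing the data. The count of 0 genes higher and 0 lower held with RLE and upper-quartile factors, without mitochondrial and structural RNA genes, without the filter, at a mean of 5 CPM, with limma-voom, with glmTreat and with the replicate block, with or without the trends. DESeq2 called 36 higher and 4 lower, 238 and 74 with the replicate block, 97 and 57 with the block and the trends removed, and 754 and 439 on the A and B pairs alone. With independent filtering at 0.05 in place of the default, a setting run first by mistake, it called 34 and 5, and 249 and 80 with the block. Over the fits that left out a library or a label, edgeR called from 0 to 306 higher and from 0 to 99 lower, with 0 in each except the fit without both libraries labelled 1. The cause was not tested for that fit or for DESeq2. In simulated counts 60 of the 200 calls of DESeq2 were false, and 64 of 225 with the block.

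Of 16 lists called, 15 were also called with the replicate block. The block ended the neuropeptide call and added glycolysis and ribosomal protein genes, and it changed no other list call and no call of a named gene by edgeR, but it raised the members called when p was adjusted over the list alone, among them from 0 to 7 mitochondrial genes. RLE and upper-quartile factors kept 16 calls. Leaving out mitochondrial and structural RNA genes gave 14 of 39 lists, with 1 call lost among those still tested. A mean of at least 5 CPM gave 17 of 39, with 1 call lost and 2 gained. Without the filter 20 of 40 lists were called, with 4 gained, and with limma-voom 21 of 40, with 5 gained. The voltage-gated channel and microglia lists passed in each leave-out fit. The test of general neuronal genes turned to lower without bound replicate 1, where their median stayed at 0.02, and the median was -0.0101 without both libraries labelled 1, with medians up to 0.45 over the leave-out fits. Neuropeptides turned without both libraries labelled 1 and ranged from -0.0939 to 0.42, nuclear-encoded respiratory chain genes turned without bound replicate 1 and without both (median 0.00113) and ranged from -0.0287 to 0.36. With the preset correlation, interferon genes turned to higher past the threshold without input replicate 1 and without both libraries labelled 1 (median 0.28). They ranged from -0.48 to 0.35 and had adjusted p = 0.988 over all libraries by camera with an estimated correlation. The cause was not tested. Of 174 named genes, 158 kept their direction in each fit that measured them. Summed counts did not separate bound from input, and the simulated recovery of 0% at a 2-fold change limits what edgeR could call.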

Other observations

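The tests of Nos3 against endothelial genes and Atg9b, those that left out the libraries labelled 1, and the division of the neuronal lists in the test of GC and length were chosen after the values they measure had been seen. The test of GC and length was first written for 4 neuronal lists together, of which 2 then passed. The rule for lost calls was changed after its results were seen. By lost calls alone the libraries labelled 1 would account for the vesicle release, glutamate receptor, projection-neuron and astrocyte calls, by a comparison with the SD of members, since dropped, for none of them, and by the interval of the median used below for the astrocyte call only. The genes below were picked after their values were seen, except where a list or a rule named them.

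Genes with very long transcripts had higher values in bound RNA, which no test of the group backs. Among genes with a mean log2 CPM over 3, the 109 with over 16000 exon bases had a median log2 fold of 0.45, with 0.78, 0.62 and 0.39 in pairs A, B and 1, against -0.03 for the 3660 genes of 2000 to 4000 bases. The pattern was weak in pair 1, where the latter had a median ratio of 0.11 and the 542 genes under 1000 bases one of 0.25, and where the ratio and exon length correlated at 0.0371, against 0.165 in pair A and 0.163 in pair B (Spearman). The 36 genes DESeq2 called higher had a median of 9315.5 exon bases, against 3418.5 for all tested genes of any level. They include the giant ubiquitin ligase genes Herc1 (1.26), Herc2 (1.17) and Mycbp2 (1.22) and the axonal motor gene Kif1a (1.22), each higher in all 3 pairs (log2 fold by DESeq2). Gm42418, a locus that overlaps ribosomal RNA sequence, took 0.0202%, 0.0209% and 0.797% of counts in input A, B and 1 and 0.0720%, 0.0591% and 2.10% in bound A, B and 1.

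Nos3 was higher in bound RNA in all 3 pairs, and neither explanation tested covers all of them. In pairs A and B, endothelial RNA in the bound fraction may account for it, since the endothelial list had a median ratio of 1.47. Of its 27 members 7 lay above Nos3, led by Flt1 at 3.50. Reads from Atg9b cannot account for it, with a summed ratio of -0.15 (-0.45 to 0.16) against 2.24 (1.97 to 2.53) for Nos3 (counting interval). That sum joins unlike pairs, since Atg9b counts went from 134 to 78 in A and from 54 to 97 in B. Nos3 counts went from 76 to 304 and from 51 to 317. In pair 1 the endothelial median was -0.43, and the upper counting bound of 26 of the 27 members lay below the Nos3 interval of 1.67 to 2.53. This argues against endothelial RNA as a whole there, although the bound of Tie1, at 0.96 (0.25 to 1.69), just reached that interval. Atg9b had a ratio of 2.01 (1.74 to 2.29) there, as high as Nos3, but a like ratio does not show shared reads. The overlap is 294 of the 4132 exon bases of Nos3 and of the 3946 of Atg9b. Bound 1 had 212 Nos3 and 484 Atg9b counts. Reads in the overlap were not counted apart, so shared reads are neither shown nor excluded for that pair. Acvrl1, an endothelial gene outside the list, was also high in pair 1 at 2.37 (2.02 to 2.74), and Nos3 in the labelled neurons themselves, as the design could give, was not tested and stays open.

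The voltage-gated channel, vesicle release, glutamate receptor and projection-neuron lists were higher in bound RNA, and the microglia, oligodendrocyte and astrocyte lists lower. Labelled neurons would give this direction, but bound and input RNA differ in more than cell type. The channel and projection-neuron lists share Scn8a and Scn1a. General neuronal genes were higher in pair 1 only, with pair medians of 0.01, -0.01 and 0.65 in A, B and 1, and were in none of these tests. GC and gene length bias is argued against as the whole cause for the channel and vesicle release lists, of which 2 of 2 still passed with the replicate block and the trends removed, and for the glial lists, of which 3 of 3 did. The channel median moved from 0.42 (0.32 to 0.56) to 0.33 (0.08 to 0.49), with camera adjusted p from 6.5e-07 to 0.0013 (95% interval over members). For vesicle release the median moved from 0.37 (0.12 to 0.49) to 0.29 (0.18 to 0.49), with adjusted p from 0.0021 to 0.014. These 2 calls thus weakened. Medians of the 3 glial lists also shrank, but their adjusted p fell. All of these calls are from camera with the preset correlation, and with an estimated correlation and the block no list passed (smallest adjusted p = 0.740). For glutamate receptor and projection-neuron lists 0 of 2 passed, their medians moving from 0.25 (0.14 to 0.51) to 0.20 (-0.03 to 0.33) and from 0.29 (0.08 to 0.37) to 0.22 (0.05 to 0.45) (95% interval over members), with adjusted p from 0.0159 to 0.209 and from 0.0217 to 0.0934. Bias and biology cannot be told apart there, since calls near the threshold ended while each new interval takes in the earlier median. The libraries labelled 1 alone are argued against as the whole cause for the channel list, with 1 of 1 passing without them and the median moving from 0.47 (0.32 to 0.57) to 0.43 (0.26 to 0.66), and for the microglia and oligodendrocyte lists, with 2 of 2. The medians of the latter shrank, however, from -0.91 (-1.12 to -0.79) to -0.41 (-0.59 to -0.35) and from -0.74 (-0.82 to -0.62) to -0.30 (-0.40 to -0.15), and the oligodendrocyte call ended without bound replicate 1 (adjusted p = 0.0805). For the astrocyte list 0 of 1 passed without the libraries labelled 1, which may account for its call, the median moving from -0.48 (-0.63 to -0.31) to -0.10 (-0.31 to 0.01) while it passed without the A and without the B libraries. For the vesicle release, glutamate receptor and projection-neuron lists 0 of 3 passed, and these libraries and biology cannot be told apart there, since the medians moved from 0.34 (0.14 to 0.54) to 0.26 (-0.06 to 0.50), from 0.27 (0.13 to 0.49) to 0.11 (-0.09 to 0.35) and from 0.21 (0.05 to 0.45) to 0.11 (0.00 to 0.41), intervals that take in the earlier medians. All these intervals redraw the members of a list as if independent and hold no error between libraries. The fits without the libraries labelled 1 used the preset correlation only. With an estimated correlation no list passed over all 6 libraries, so the readings above hold under the preset correlation alone.

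Th, Dbh and Slc6a2 were higher in bound RNA in all 3 pairs, and a candidate explanation is that some labelled cells were noradrenergic. Of further genes of such neurons, 6 not looked at before (Cyb561, Tfap2b, Adra2a, Hcrtr1, Ret and Calcr) had a median log2 fold of 0.45 with the replicate block, at percentile 99.0 of 10000 random lists matched on level, whose 95th percentile was 0.31. Tfap2b had ratios of 1.12, 0.40 and 1.09, Cyb561 was also above 0 in each pair, Ret had a log2 fold of only 0.10, and Adra2a, Hcrtr1 and Calcr were below 0 in pair A and above it in B and 1. Other neurons express several of these genes, and general neuronal genes had a blocked median of 0.25, so a rise of neurons at large stays open in part.

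Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. With edgeR the real split called 0 genes and the highest other 0, so all 10 splits gave as many. With DESeq2 the real split called 40 genes and the highest other 135, and 5 splits gave as many as the real one. That highest split set input A, input B and bound B against bound A and both libraries labelled 1, which points to the distance of the latter from the rest. With the replicate block, DESeq2 called 312 genes in the real split and at most 13 in the other 3 of the 4 splits that part all 3 pairs, and 1 of the 4 gave as many. These other 3 swap bound and input within 1 pair. Camera with the preset correlation called 16 lists in the real split and 23 in the highest other, and 4 of the 10 splits gave as many. With the replicate block it called 17 lists in the real split and 13, 16 and 14 in the other 3 that part all 3 pairs.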
